A study of Mus musculus with 6 samples.

How the data were processed

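RNA was sequenced from E14 mouse embryonic stem cells (ESCs), an established line, and from Hnrnpf knockout cells, either kept in leukemia inhibitory factor (LIF, the cytokine that holds mouse ESCs in self-renewal) or grown for 4 days without it. The 6 libraries form 4 groups: 1 wild type and 2 knockout libraries with LIF, and 1 wild type and 2 knockout libraries after LIF removal. Per the labels' protocols, total RNA was used and sequenced as 150 bp paired-end reads on an Illumina NovaSeq. The labels do not say whether the libraries of a group came from separate cultures or clones, so p-values measure the spread between these libraries, which may be technical. Nor do they say whether a knockout number marks the same clone in both media; if it does, the 4 knockout libraries come from 2 clones, and the p-values of the knockout effect over both media do not measure the spread between 4 independent samples.

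The authors deposited 1 table of FPKM, fragments scaled to transcript length and to the total of mapped fragments, with 1 value per gene symbol and library for 25170 symbols. Per the submitters' processing notes, the tools were STAR and Cufflinks and the genome build was mm10; versions, parameters and the gene annotation are not given in the sources used here. The FPKM of a library summed to between 456155 and 556318. No read counts were used, so no interval for counting error was given. Where a low gene's value is a whole multiple of what 1 read is worth, ratios between libraries give relative depth: against the wild type library with LIF, it was 1.074 and 1.082 in the knockout libraries with LIF, 1.017 in the wild type library after LIF removal, and 0.910 and 0.846 in the knockout libraries after LIF removal. Among genes under 0.3 FPKM in both libraries, between 12.2% and 15.5% lay within 0.01 (log2) of the commonest ratio. The number of reads behind a value stays unknown.

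The table gives low values for several genes with many near-identical copies in the genome. Gapdh lay between 1.11 and 2.58 FPKM, Rpl3 between 1.24 and 3.85 and Ftl1 between 0.656 and 5.99, while Actb lay between 1133 and 1468. Of 75 ribosomal protein genes, 18 had a mean under 10 FPKM, and 2 genes had at least 20 FPKM in a library and 0 in another. Values of genes with pseudogenes or close paralogs are therefore uncertain, and an exact 0 may be a failed estimate. Whether counting used strand is not given, so antisense and overlapping genes may share reads.

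Values were analysed as log2(FPKM + 1) without further scaling, and differences on this scale understate the change of genes with low values. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11785 in all. Tests were made with limma 3.58.1 in R 4.3.3 (linear models, empirical Bayes moderation with an intensity trend, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A fit with 4 groups gave the knockout effect in each medium, the LIF removal effect in knockout cells and the difference of responses. It has 2 residual and 4.70 prior degrees of freedom, all from the knockout libraries, and the lone wild type library of each medium is assumed to vary like them. A fit of genotype and medium as added terms gave the average effect of each, with 3 residual and 5.08 prior degrees of freedom. LIF removal in wild type cells compares 1 library with 1, so no test was made and genes were counted by an absolute log2 difference of at least 1.

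Before the data were examined, 27 gene lists with 555 entries were fixed, of which 541 entries were found. Lists were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, with adjustment over the 25 lists tested in a comparison. With an estimated correlation, camera has only the residual degrees of freedom of the fit, 2 or 3, and so little power. No list passed it in any comparison, so failing it does not argue against a list. The preset lies below many of the estimated correlations, so its p-values may be too small. In the untested comparison, a list's median was placed among 10000 random lists matched on mean expression. The genes named were also fixed by rule: Hnrnpf, a panel of lineage and pluripotency genes in each comparison, the 8 largest rises and 8 largest falls past the threshold whose groups do not overlap, without unnamed gene models, ribosomal, mitochondrial and small RNA symbols, and up to 4 members with the lowest p of each list described. The panel genes Gata6, Sox17 and Sox1 had a mean under 1 FPKM and were not tested. In the comparison without a test, the largest 8 in each direction had a mean of at least 5 FPKM, and a comparison without calls names the 5 genes with the lowest p, in both cases with unnamed gene models kept. Some genes that these rules select are not reported here.

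The scripts were tested on simulated data made from these libraries, with 200 genes changed by a known amount in each of 20 draws over 11785 genes. For the knockout effect over both media, 87.9% of genes changed by a log2 of 1 and 99.85% of those changed by 2 were recovered, with 7.10% of calls false. For the knockout effect with LIF, 55.05% and 98.0% were recovered, with 8.13% of calls false. For LIF removal in knockout cells the shares were 78.0% and 99.65% (7.74% false), and for LIF removal over both genotypes 93.65% and 99.9% (6.79% false). The false shares all lie above the 0.05 of the threshold. The simulated noise was independent and normal, with each gene's moderated spread, and had no effect of the knockout number. It was also the same in wild type and knockout libraries, which cannot be checked with 1 wild type library per medium. The recovered shares may therefore be too high for these data, and the false shares too low. Coordinates are those of GENCODE's mouse annotation on the mm10 assembly, matched by symbol, with 200 tested genes unmatched. Figures and summaries of the alternatives were made in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

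Alternatives were another pseudocount (0.1), no filter or a filter at a mean of 5 FPKM, median ratio scaling, quantile normalization, moderation without the trend, a fit of the compared groups only, the number in the knockout labels as a block, and each library left out in turn. Leaving out both knockout libraries of a number, or all genes of chromosomes 6, 8 and 11, was chosen after seeing the data. An interferon-inducible gene list was also added after seeing the data.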

Results

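Gene expression was measured by RNA-seq in 6 libraries of mouse ESCs to compare the effect of Hnrnpf loss in pluripotent cells and in cells differentiating for 4 days after LIF removal. Hnrnpf encodes an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family that binds G-rich RNA and takes part in splicing. Values are FPKM as deposited. Each medium has 1 wild type library, whose values have no replicate error, and 2 knockout libraries, here called 1 and 2 by their number, whose means are given with their SD (n = 2). Of the variance between libraries, 51.9% lay on a principal component that ordered libraries by medium and 25.7% on a component that separated wild type from knockout libraries.

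Hnrnpf (chromosome 6, 117900324 to 117925622) stood at 342 FPKM in the wild type library with LIF and 335 after LIF removal. In the knockout libraries it was 98.7 and 37.1 FPKM with LIF and 95.2 and 27.8 after LIF removal, or 28.9%, 10.8%, 28.4% and 8.28% of the wild type value in the same medium. All 4 knockout libraries thus lay below both wild type libraries, with transcript remaining in each. Over both media Hnrnpf fell by 2.58 on the log2 scale (SE 0.49, limma adjusted p = 0.0200); with the 4-group fit the difference was -2.48 (SE 0.76, adjusted p = 0.183) with LIF and -2.68 (SE 0.76, adjusted p = 0.181) after LIF removal. The labels do not give the deleted part of the gene, so residual FPKM cannot be set against it.

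The close paralog Hnrnph1 (chromosome 11, 50376990 to 50386528) was higher in every knockout library: 256 FPKM in wild type cells with LIF against 528 ± 43.0 (SD, n = 2) in knockout cells, and 281 against 554 ± 5.47 after LIF removal. Over both media it rose by 1.01 on the log2 scale (SE 0.10, adjusted p = 0.00440). Genes of chromosome 11 as a whole were also higher in these libraries, by a median of 0.44 to 0.48 on the log2 scale. Hnrnph2, on the X chromosome, did not pass the threshold (0.11, SE 0.11, adjusted p = 0.580). Of the 25 tested members of the hnRNP list, 2 were higher and 3 lower over both media, with the same counts adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.592, camera; 0.919 with an estimated correlation).

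**Figure D1:**
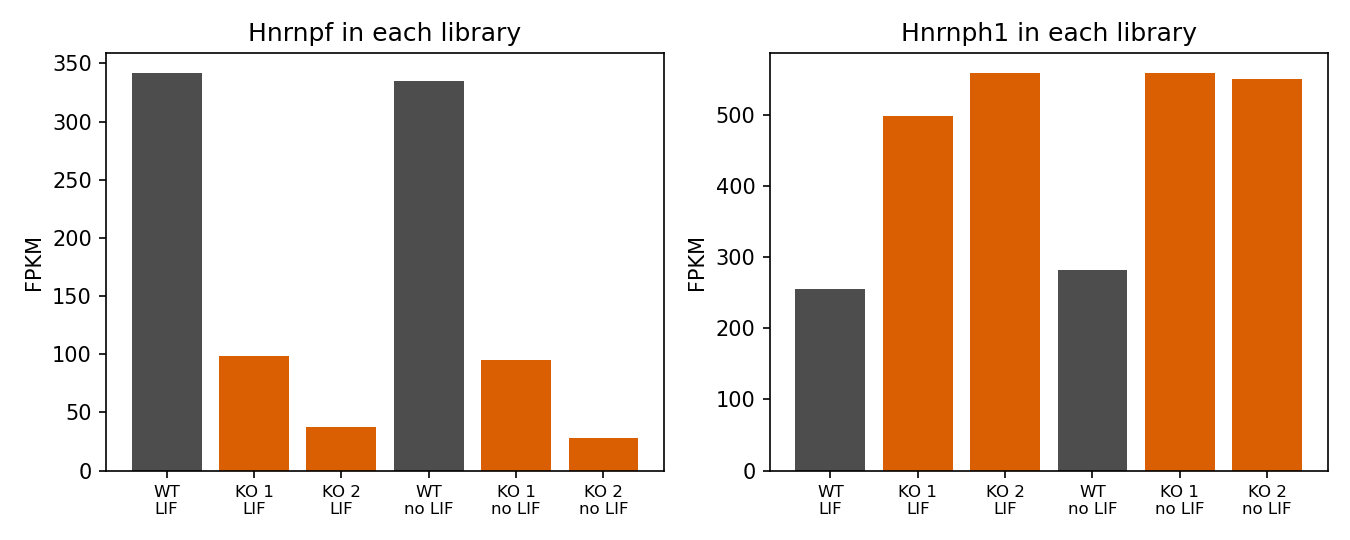
FPKM (bars, from 0) of Hnrnpf and Hnrnph1 in each of the 6 libraries, with wild type in grey and knockout in orange. Hnrnpf lies between 27.8 and 98.7 FPKM in the knockout libraries against 335 and 342 in wild type, and Hnrnph1 between 498 and 559 against 256 and 281.

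Knockout against wild type over both media, with 4 knockout and 2 wild type libraries, was the widest comparison of genotype. Of 11785 genes, 1232 passed the threshold, 682 higher and 550 lower in knockout cells, and 154 and 72 of these changed at least by a log2 of 1. The split was 687 higher and 414 lower after quantile normalization, and 727 and 475 with median ratio scaling. The largest rises were Serpina3m (5.14, SE 0.28, adjusted p = 0.000810), a serine protease inhibitor, the imprinted genes Mest (3.32), Rian (3.08) and Meg3 (3.05), Pttg1 (securin, 2.81), Pnma5 (2.41), Fmr1nb (2.29) and Tex19.1 (2.21), a germ cell and ESC gene. Serpina3m was at 0.164 and 0.108 FPKM in wild type cells and between 27.5 and 58.9 in knockout cells. After Hnrnpf, the largest falls included Apopt1 (-2.18), Fgf15 (-1.71), a fibroblast growth factor of the formative list, Grb10 (-1.69) and Cdkn1c (-1.60), both imprinted growth inhibitors, Tcl1 (-1.67), a naive pluripotency marker, and Macrod1 (-1.44). The core factors were not called: the difference was -0.38 for Pou5f1 (adjusted p = 0.0998), -0.35 for Sox2 (0.0976) and 0.12 for Nanog (0.686). Neither were Esrrb (-0.30, adjusted p = 0.449), Klf4 (0.68, 0.196), Zfp42 (0.09, 0.859), Tfcp2l1 (-0.52, 0.148), Fgf5 (0.23, 0.731), Otx2 (-0.06, 0.864) and Dnmt3b (0.07, 0.884). Lineage genes of the panel did not pass either: T gave 1.06 (0.149), Eomes -0.39 (0.275), Gata4 0.26 (0.489), Pax6 -0.45 (0.127), Nes 0.25 (0.626), Cdx2 0.61 (0.197), and the cell cycle inhibitor Cdkn1a 0.38 (0.220). With either wild type library left out, the fit compares genotypes only in the medium of the remaining one. It then repeats a single-medium comparison given below and is not a separate check. Without knockout library 2 with LIF the count was 560, and without a filter on low values it was 335.

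The genes called higher were unevenly spread over the genome. Of the 682, 365 (53.5%) lay on chromosome 11, which holds 8.61% of the tested genes with a known position. That is 365 higher and 4 lower among the 998 tested on this chromosome (odds ratio 18.98 for being called higher, Fisher's exact test, two-sided, p = 1.11e-226; neighbouring genes are not independent). The median of its genes was 0.46 and 0.48 above wild type in knockout libraries 1 and 2 with LIF, and 0.44 and 0.48 after LIF removal. On chromosome 6 between 50 and 100 Mb the median was 0.52 to 0.70 higher in the 4 libraries, with 91 genes called higher and 1 lower. The first 30 Mb of chromosome 8 had medians of -0.30 to -0.39 in the 4 libraries, with 1 gene called higher and 19 lower, and the rest of chromosome 8 had medians of -0.39 and -0.47 in the knockout libraries numbered 2 against 0.12 and -0.02 in those numbered 1. The bounds within chromosomes 6 and 8 were drawn after seeing these data, so the medians and counts describe the stretches and do not test them. Across the other 17 chromosomes a library's median lay between -0.18 and 0.04. Without the genes of chromosomes 6, 8 and 11, a choice made after seeing the data, 551 genes passed, 167 higher and 384 lower. Pttg1, Tex19.1, Hnrnph1 and Grb10 are on chromosome 11, and Grb10 was lower there.

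**Figure D2:**
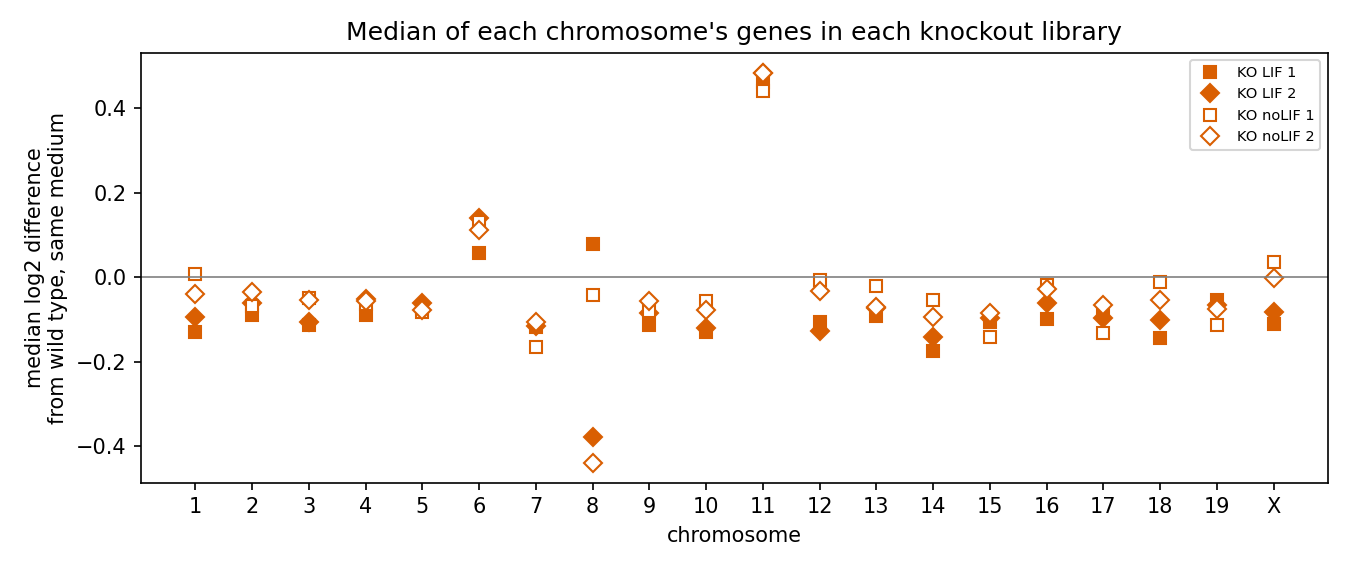
Median log2 difference from the wild type library of the same medium (vertical axis) for the genes of each chromosome (horizontal axis) with a mean of at least 5 FPKM, with 1 point for each knockout library. Chromosome 11 lies between 0.44 and 0.48 in all 4 libraries, and chromosome 8 near -0.38 and -0.44 in the libraries numbered 2.

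Imprinted genes, expressed from a single parental allele, were the list that passed in the same comparison. Of 22 tested, 9 were higher and 2 lower, with 13 higher and 2 lower adjusted over the list alone. The list median was 0.81 (camera adjusted p = 5.14e-06; adjusted p = 0.919 with an estimated correlation). Meg3, Rian and Mirg, non-coding RNAs transcribed from the maternal allele of the Dlk1-Meg3 cluster (Meg3 to Mirg, chromosome 12, 109541001 to 109749460), rose by 3.05, 3.08 and 2.77, and the paternally expressed Dlk1 of the same cluster (109452823 to 109463336) by 1.06 (adjusted p = 0.0208). Mest, a paternally expressed gene (chromosome 6, 30723547 to 30748465), rose from 19.4 FPKM in wild type cells with LIF to 139 ± 19.9 (SD, n = 2) and from 15.2 to 238 ± 4.22 after LIF removal. The other called genes were Igf2 (1.52), Zrsr1 (1.20), Ndn (0.72) and Peg10 (0.67), higher, and the maternally expressed Grb10 (-1.69) and Cdkn1c (-1.60), lower. Of the 11, 7 lie on chromosomes other than 6, 8 and 11.

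**Figure D3:**
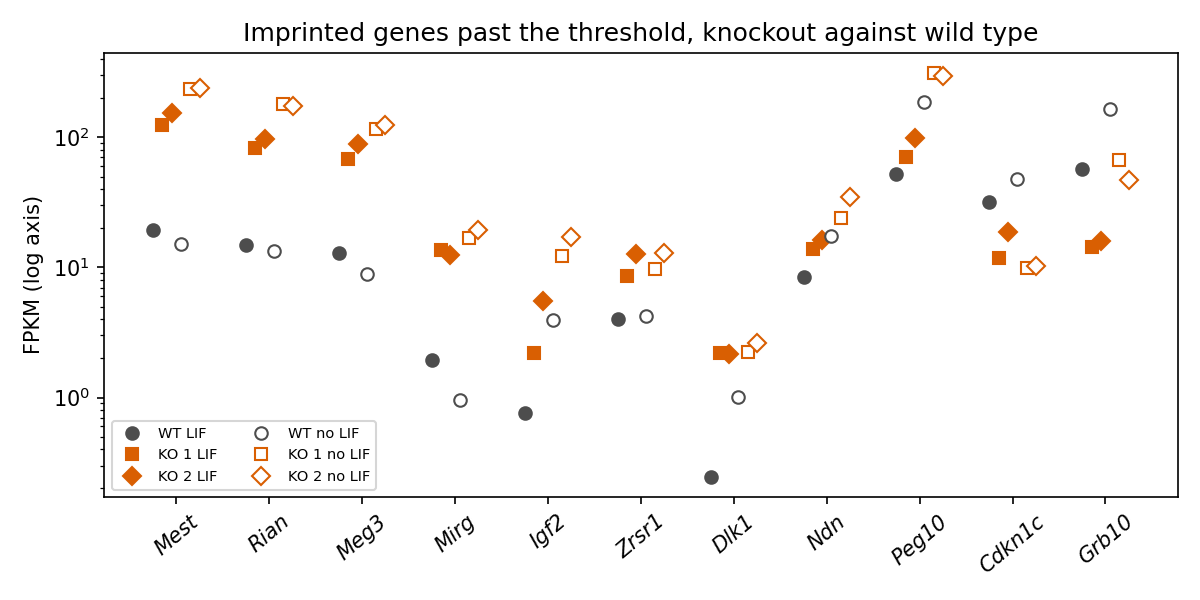
FPKM (log axis) of the 11 imprinted genes past the threshold for knockout against wild type, with 1 symbol for each library. Meg3 lies at 12.9 and 8.92 FPKM in the wild type libraries and between 67.7 and 124 in the knockout libraries, while Grb10 lies at 57.3 and 165 FPKM in wild type and between 14.3 and 66.6 in the knockout libraries.

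With LIF alone, 5 genes passed, all higher in knockout cells: Serpina3m (5.24, SE 0.43, adjusted p = 0.0233), Mest (2.77), Rian (2.54), Meg3 (2.49) and Mirg (2.26, adjusted p = 0.0494). Meg3 rose from 12.9 FPKM to 77.9 ± 14.4 (SD, n = 2). At an unadjusted p under 0.05 there were 1972 genes. The imprinted list was higher (4 of 22 called, 10 higher and 2 lower adjusted over the list alone; median 0.62, camera adjusted p = 8.05e-06), as was the formative and primed epiblast list, genes of the state that follows naive pluripotency, with none of 15 called and 5 higher and 1 lower adjusted over the list alone (median 0.42, adjusted p = 0.0116). With an estimated correlation neither passed (adjusted p = 0.990 for both). Formative members with the lowest p were Lef1 (1.03), Dnmt3a (0.78), Zic2 (0.69) and Fgf15 (-1.38), none past the threshold (adjusted p = 0.112 to 0.119). The naive list had a median of -0.38 and did not pass (adjusted p = 0.123). Of the panel none passed: Nanog -0.15 (0.746), Esrrb -0.65 (0.348), Klf4 0.05 (0.959), Zfp42 0.04 (0.971), Tfcp2l1 -0.94 (0.119), Pou5f1 -0.16 (0.652), Sox2 -0.44 (0.270), Fgf5 0.82 (0.429), Dnmt3b 0.71 (0.140), T 0.46 (0.733) and Nes 0.93 (adjusted p = 0.177). Otx2 gave 0.32 (0.415), Eomes -0.15 (0.844), Gata4 0.34 (0.655), Pax6 -0.27 (0.613), Cdx2 0.63 (0.515), Cdkn1a 0.10 (0.873), Hnrnph1 1.04 (0.0964) and Hnrnph2 0.25 (adjusted p = 0.493). The count was 0 without a filter and 0 without the intensity trend, 14 without knockout library 1 with LIF, and 9 without either knockout library after LIF removal.

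After LIF removal, 7 genes passed, all higher in knockout cells, and 1826 at an unadjusted p under 0.05. They were Serpina3m (5.04), Mest (3.88, SE 0.17, adjusted p = 0.00110), Rian (3.63), Meg3 (3.61), Mirg (3.28), Mks1 (1.95) and Upp1 (1.65), the last being uridine phosphorylase. Mks1 and Upp1 lie on chromosome 11. Upp1 rose from 82.3 FPKM to 261 ± 23.5 (SD, n = 2). The imprinted list passed (4 of 22 called, 13 higher and 2 lower adjusted over the list alone, median 0.89, camera adjusted p = 5.53e-07; adjusted p = 0.864 with an estimated correlation). The naive list had a median of 0.09 (adjusted p = 0.437) and the formative list of -0.39 (0.172). Panel values short of the threshold included Klf4 1.32 (0.154), Nanog 0.38 (0.404), Dnmt3b -0.57 (0.216), Pou5f1 -0.60 (0.154), Eomes -0.63 (0.361), Nes -0.42 (0.521), T 1.65 (0.239) and Cdkn1a 0.66 (adjusted p = 0.252). Esrrb gave 0.04 (0.967), Zfp42 0.14 (0.910), Tfcp2l1 -0.10 (0.882), Sox2 -0.26 (0.528), Fgf5 -0.36 (0.758), Otx2 -0.44 (0.299), Gata4 0.18 (0.848), Pax6 -0.63 (0.263), Cdx2 0.59 (0.553), Hnrnph1 0.98 (0.136) and Hnrnph2 -0.03 (adjusted p = 0.951). The count was 13 with a pseudocount of 0.1, 0 without a filter, 4 without the trend and 16 when either knockout library with LIF was left out or the compared groups were fitted alone. Across genes, the effects in the 2 media, which share no library, correlated with a Spearman rho of 0.591 (0.469 with number 1 alone and 0.643 with number 2), and genes are not independent replicates. All tested genes are included, among them those of the chromosome stretches shifted in both media. The correlation therefore does not separate an effect of Hnrnpf loss from other differences between the lines. All 5 genes called with LIF were among the 7 called after LIF removal. Both counts come from 1 fit with the same error for a gene, so the 0.00297 shared genes of independent lists is not the value that chance gives here.

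LIF removal over both genotypes, 3 libraries against 3, changed 2523 genes, 1029 higher and 1494 lower, with 313 in each direction at a log2 of at least 1. After quantile normalization the split was 1160 higher and 1179 lower, so the excess of lower genes depends on scaling. Genes of the naive state fell: 19 of the 20 tested members of the naive list were lower (median -1.18, camera adjusted p = 6.94e-10, and adjusted p = 0.580 with an estimated correlation), among them Tcl1 (-2.40), Klf2 (-1.64), Pecam1 (-1.46) and Dppa5a (-1.31). The panel's Esrrb (-1.77, adjusted p = 0.00230), Tfcp2l1 (-1.24), Zfp42 (-1.23), Klf4 (-1.12), Sox2 (-0.94), Pou5f1 (-0.55) and Nanog (-0.50, adjusted p = 0.0470) all fell. Members of the LIF-STAT3 pathway fell too, 7 of 13 with 1 higher (median -0.56, adjusted p = 0.00815, and adjusted p = 0.580 with an estimated correlation), including the kinases Pim3 (-0.67) and Pim1 (-0.88), the adhesion molecule Icam1 (-1.14) and the receptor Lifr (-0.86). The formative and primed epiblast list was higher, with 6 of 15 higher and 1 lower (median 0.44, adjusted p = 0.00875, and adjusted p = 0.580 with an estimated correlation). The members with the lowest p were Fgf5 (3.56, SE 0.34, adjusted p = 0.00116), Sall2 (1.67), Lef1 (1.18) and Wnt8a (1.79). Adjusted over the list alone, all 20 naive genes were lower, 8 LIF-STAT3 genes were lower and 1 higher, and 8 formative genes were higher and 1 lower. Dnmt3b (0.84), T (Brachyury, 2.23), Eomes (0.93) and Nes (nestin, 2.01) rose, and Otx2 (0.44, adjusted p = 0.0949), Pax6 (-0.38, 0.119), Gata4 (0.13, 0.683), Cdx2 (0.81, 0.0592), Cdkn1a (0.48, 0.0777), Hnrnph1 (0.09, 0.489), Hnrnph2 (0.25, 0.134) and Hnrnpf (-0.16, 0.831) did not pass.

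The largest rises were Tagln (3.58), an actin-binding protein, Fgf5, Thbs1 (3.24) and Ccn1 (3.09), matricellular proteins, the activin antagonist Fst (2.98), Colec12 (2.59), Sema6a (2.53) and Efemp1 (2.47). The mesenchymal transition list had 7 of 20 higher and 3 lower (median 0.51, adjusted p = 0.00385, and adjusted p = 0.580 with an estimated correlation), with Ccn2 (2.07), Tpm1 (2.05) and Cnn1 (1.87). The epithelial junction list had 5 of 16 higher and 3 lower (median 0.36, adjusted p = 0.0447, and adjusted p = 0.580 with an estimated correlation), with Krt19 (2.10), Cldn7 (1.02) and Cldn6 (0.997) higher and Tjp3 (-1.16) lower. Of 21 p53 targets, 10 were higher and 1 lower (median 0.48, adjusted p = 0.00385, and adjusted p = 0.580 with an estimated correlation), with Perp (2.31), Plk2 (1.47) and Ccng1 (1.16) higher and Tigar (-0.79) lower. Splicing regulators (7 of 32 higher, none lower; median 0.11, adjusted p = 0.00815) included Celf2 (1.21), Mbnl1 (0.96), Srsf12 (0.94) and Khdrbs1 (0.62), and imprinted genes (8 of 22 higher, none lower; median 0.46, adjusted p = 0.000175) included Nnat (2.39), Peg10 (1.84), Grb10 (1.72) and Igf2 (1.67). With an estimated correlation neither of these lists passed (adjusted p = 0.580 for each). Adjusted over the list alone, 10 mesenchymal genes were higher and 4 lower, 7 epithelial junction genes higher and 3 lower, 13 p53 targets higher and 2 lower, 8 splicing regulators higher and 9 imprinted genes higher. Fibroblast (feeder) markers had 2 of 7 higher and did not pass as a list (median 0.55, adjusted p = 0.122). The largest falls were Mymx (-3.28), Stra8 (-2.50), a meiotic gene induced by retinoic acid, Gjb1 (-2.49), Septin1 (-2.46), Krt42 (-2.44), Tcl1, Fam25c (-2.37) and Dlgap3 (-2.25). The count was 817 without the wild type library with LIF and 821 without the one after LIF removal, where the effect comes from the knockout libraries alone. It was 1395 without knockout library 1 with LIF and 1665 without knockout library 2 after LIF removal.

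In knockout cells alone, 816 genes changed on LIF removal, 359 higher and 457 lower, and 359 higher and 354 lower after quantile normalization. Tagln (3.48, SE 0.70, adjusted p = 0.0386), Thbs1 (3.32), Fgf5 (3.17), Ccn1 (3.06), Efemp1 (3.01), Fst (2.66), Ppp4r4 (2.64) and T (2.63) rose most, and Mymx (-2.62), Tcl1 (-2.50), Stra8 (-2.49), Fam25c (-2.46), Mt4 (-2.46), Krt42 (-2.41), Septin1 (-2.24) and Dlgap3 (-2.15) fell most. Fgf5 went from 3.94 ± 2.33 to 42.3 ± 15.8 FPKM (SD, n = 2). The naive list had 10 of 20 lower and none higher (median -0.93, camera adjusted p = 3.66e-09, and adjusted p = 0.700 with an estimated correlation), with Esrrb (-1.54), Klf2 (-1.48) and Tfcp2l1 (-0.96) called, and Nanog (-0.33, adjusted p = 0.241), Klf4 (-0.70, 0.153) and Zfp42 (-1.19, 0.0768) not. The core factors Sox2 (-0.88) and Pou5f1 (-0.70) fell. Nes rose (1.56) and Dnmt3b (0.41, 0.132), Otx2 (0.18, 0.446) and Eomes (0.77, 0.0991) did not pass. Neither did Cdkn1a (0.67, 0.0833), Cdx2 (0.80, 0.192), Pax6 (-0.50, 0.149), Gata4 (0.08, 0.883), Hnrnpf (-0.23, 0.848), Hnrnph1 (0.07, 0.734) and Hnrnph2 (0.16, 0.481). Also past the threshold were the imprinted list (9 of 22 higher, adjusted p = 6.55e-06; Peg10 1.85, Grb10 1.82, Rian 0.97, Plagl1 1.97) and p53 targets (9 of 21 higher, 1 lower, adjusted p = 0.000530; Trp53inp1 1.23, Plk2 1.54, Ccng1 1.31, Pmaip1 1.06). Neither passed with an estimated correlation (adjusted p = 0.700 for each). The mesenchymal transition list (4 of 20 higher, adjusted p = 0.00562; Ccn2 1.94, Tpm1 2.13, Cnn1 1.51), splicing regulators (4 of 32 higher, adjusted p = 0.00562; Celf2 1.28, Mbnl1 1.09), glycolysis (1 of 22 higher, 2 lower, adjusted p = 0.0129; Slc2a1 0.9995, Aldoa -0.66, Hk1 -0.93) and the LIF-STAT3 list (2 of 13 lower, adjusted p = 0.0195; Icam1 -0.89, Pim3 -0.66) passed too. With an estimated correlation none of these 4 passed (adjusted p = 0.700 for each). Adjusted over the list alone, 17 naive genes were lower, 11 imprinted genes higher, 13 p53 targets higher and 2 lower, 7 mesenchymal genes higher and 2 lower, and 6 splicing regulators higher. Likewise adjusted over the list alone, 3 glycolysis genes were higher and 12 lower, and 1 LIF-STAT3 gene was higher and 8 lower. Gapdh, whose low values are uncertain, is among the glycolysis genes tested. The count was 0 without a filter, 138 and 539 without knockout library 1 or 2 with LIF, and 440 and 124 without knockout library 1 or 2 after LIF removal.

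In wild type cells the same comparison has 1 library in each medium and no test. By size, 985 genes differed by a log2 of at least 1, 448 higher and 537 lower after LIF removal. The largest differences upward were Gm51018 (4.75; listed at 0 with LIF), Fgf5 (4.35), Tagln (3.78), Fst (3.61), Nnat (3.50), Sema6a (3.33), Pim2 (3.31) and Ccn1 (3.15), and downward Mymx (-4.60), Septin1 (-2.91), B230311B06Rik (-2.80), Pltp (-2.53), Polr3gl (-2.53), Stra8 (-2.52), Nphs1 (-2.52) and Krt42 (-2.51). The naive list had a median of -1.47, below all 10000 random lists, and the formative list of 0.94, above all of them. Esrrb differed by -2.23, Klf4 by -1.96, Tfcp2l1 by -1.81, Zfp42 by -1.29, Sox2 by -1.06, Nanog by -0.86 and Pou5f1 by -0.25, against Dnmt3b 1.69, T 1.43, Eomes 1.25, Nes 2.91 and Otx2 0.94. The remaining panel genes differed by 0.83 (Cdx2), 0.44 (Hnrnph2), 0.24 (Gata4), 0.14 (Hnrnph1), 0.11 (Cdkn1a), -0.14 (Pax6) and -0.03 (Hnrnpf). Also above all random lists were the trophoblast (0.82), epithelial junction (0.52), mesenchymal transition (0.51) and imprinted (0.41) lists, and LIF-STAT3 (-0.67) was below all. The primitive streak list had a median of 1.25 (percentile 99.98), with 4 of 7 genes higher and 2 lower by a log2 of at least 1. The primitive and visceral endoderm list had a median of 0.49 (percentile 99.74). The number of genes was 1550 with a pseudocount of 0.1 and 536 among genes with a mean of at least 5 FPKM.

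**Figure D4:**
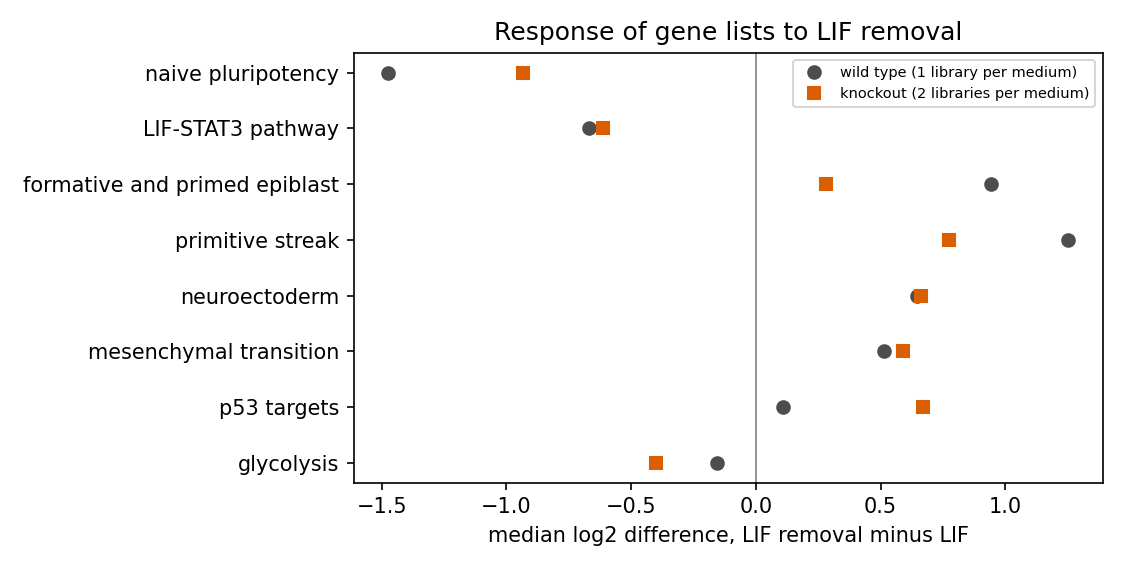
Median log2 difference between LIF removal and LIF (horizontal axis) of the tested genes of 8 lists, in wild type (grey circles, 1 library per medium) and knockout cells (orange squares, 2 per medium). The naive list lies at -1.47 and -0.93 and the formative and primed epiblast list at 0.94 and 0.28.

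The difference of the LIF removal response between knockout and wild type cells, the question of the series title, gave no gene past the threshold with limma (lowest adjusted p = 0.9996), and 340 at an unadjusted p under 0.05. That is fewer than a share of 0.05 of the 11785 genes. The simulation did not cover this comparison, so its power is unknown. The lack of calls therefore does not show that the responses were equal. The genes with the lowest p, none of which passed, were H4c8 (-3.30), Lsm7 (2.95), Mymx (1.98), 1700019A02Rik (-2.82) and Dynlt1f (2.46). The formative and primed epiblast list had a smaller response in knockout cells with the preset correlation (median difference -0.72 over 15 genes, camera adjusted p = 5.09e-08, and adjusted p = 0.730 with an estimated correlation). Dnmt3b, a de novo DNA methyltransferase, went from 117 to 379 FPKM in wild type cells and from 192 ± 26.5 to 256 ± 27.6 (SD, n = 2) in knockout cells (difference -1.28, SE 0.26). Dnmt3a gave -0.91, Otx2 -0.76, Zic2 -0.61 and Fgf5 -1.18. Naive genes had a median difference of 0.47 (adjusted p = 0.00282, and adjusted p = 0.730 with an estimated correlation). Members gave Tbx3 1.61, Klf4 1.27, Tfcp2l1 0.85, Spp1 0.53, Esrrb 0.69 and Nanog 0.54. Klf4 was at 13.2 FPKM with LIF and 2.65 without in wild type cells, and at 13.9 ± 2.94 and 8.33 ± 3.00 (SD, n = 2) in knockout cells. Also past the threshold were neuroectoderm (median -0.36, adjusted p = 0.0427; Nes -1.34, Sox11 -0.82, Tubb3 -0.65, Sox21 1.16), glycolysis (median -0.22, adjusted p = 0.0246; Ldha -0.67, Ldhb 0.76, Pgam1 -0.55, Pkm -0.40) and p53 targets (median 0.20, adjusted p = 0.0246; Trp53inp1 1.01, Pmaip1 1.07, Eda2r 0.61, Mdm2 0.50). With an estimated correlation these 3 lists did not pass either (adjusted p = 0.730 for each), and no gene of the 5 lists passed over all genes tested. The glycolysis list includes Gapdh, one of the genes with near-identical copies whose values are uncertain. Adjusted over the list alone, 1 formative gene (Dnmt3b) was lower and none of the other 4 lists had a call. The panel's Pou5f1 gave -0.44, Sox2 0.19, Zfp42 0.10, T 1.20, Eomes -0.48, Gata4 -0.16, Pax6 -0.36, Cdx2 -0.03, Hnrnpf -0.20, Hnrnph1 -0.07, Hnrnph2 -0.28 and Cdkn1a 0.56, all with an adjusted p of 0.9996. Without knockout library 1 with LIF, 1 gene passed.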

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

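Of the tests in this part, those of scaling and of an extra copy for chromosome 11, all 3 for imprinted genes, and those of the wild type libraries and of genotype for the formative list were chosen after the results were seen. No group has 4 libraries, so no library could be tested as standing apart from its group.

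The response to LIF removal differed between genotypes in the interaction test of 5 lists: formative and primed epiblast (-0.72), naive pluripotency (0.47), neuroectoderm (-0.36), glycolysis (-0.22) and p53 targets (0.20), as medians of the difference, knockout minus wild type. No single gene passed, and no list passed with an estimated correlation between genes. With 2 residual degrees of freedom the test with an estimated correlation has little power, so it leaves these lists undecided. The formative list is the pattern with the lowest p. Library scaling is argued against, since the median was -0.76 after quantile normalization. A single knockout number behind the difference of responses is argued against too, since the number with the smaller difference still gave -0.60. By library, the list lay 0.36 (number 1) and 0.64 (number 2) above wild type with LIF. After LIF removal it lay at -0.49 (number 1) and -0.07 (number 2), so its position below wild type there rested mostly on number 1. Taken over both numbers, the list lay 0.42 above wild type with LIF and -0.39 after LIF removal. The smaller of these sizes (0.395) is close to the largest gap between the knockout numbers in a medium (0.419), so a wild type library that stands apart remains open. A difference due to genotype cannot be told apart from it with 1 wild type library in each medium.

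The shift of chromosome 11 in all 4 knockout libraries covers 365 of the 682 genes called higher in knockout cells over both media. Scaling would move all chromosomes, and chromosome 11 lay 0.507 above the highest median of the other 17. GC content, transcript length and expression level, fitted on the other chromosomes, left a median of 0.578 (0.474 before the fit). An extra copy of the chromosome would raise all of it, and 3 copies in place of 2 would give 0.585. Over all 4 libraries, the lowest median of the 12 windows of 10 Mb with at least 20 genes was 0.291 and the highest 0.665. The window from 10 to 20 Mb, with 11 genes, lay between 0.406 and 0.476. A candidate explanation is therefore a gain of chromosome 11 in the cells behind the knockout libraries, carried along with the genotype; no DNA was measured, and a broad effect of Hnrnpf loss on this chromosome was not tested.

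Imprinted genes changed beyond the shifted chromosomes, since 7 of the 11 called lie elsewhere. That argues against the copy number of chromosomes 6, 8 and 11 as the whole cause. The other 17 chromosomes were judged only by the median of a whole chromosome, which can hide a shorter stretch. A local change of copy number around the 7 genes was therefore not tested. Of these, Meg3, Rian, Mirg and Dlk1 share a cluster and are not independent. Mest and Peg10 lie in the first 50 Mb of chromosome 6, where medians in the knockout libraries were between -0.082 and -0.006. All 11 stayed called after quantile normalization, which argues against scaling. A further candidate is imprints that differ between the wild type line and the line behind the knockout libraries. All 11 moved the same way in both knockout libraries with LIF. They were called on these same libraries, so the shared direction was largely fixed in advance and does not test that explanation. With a single wild type line, that explanation and an effect of Hnrnpf loss cannot be told apart. Of the 11, 3 maternally expressed genes rose and 2 fell, while the 6 paternally expressed genes all rose.

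The 2523 genes changed by LIF removal over both genotypes were compared with the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1 gave as many genes, the real one, and the highest other gave 1 gene. Every other split has libraries of both media on each side, so the LIF effect enters its error and few calls could arise. The contrast therefore does not show how many genes chance would give, and 10 splits are too few for a share under 0.05.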

How the results depend on the processing

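The alternatives that left out both knockout libraries of a number, or the genes of chromosomes 6, 8 and 11, were chosen after seeing the data. The correlation of the knockout effects between media kept its sign in all 4 alternatives, LIF removal over both genotypes stayed within 1.5 times its count in all 10 other settings, and the difference of responses gave 0 genes in all 8. The cause of the changes below was not tested, except where fewer libraries or genes were used. Counts of knockout against wild type were, with LIF (5 as reported), 0 without a filter, 0 without the intensity trend and 8 without chromosomes 6, 8 and 11; after LIF removal (7 as reported), 13 with a pseudocount of 0.1, 0 without a filter, 4 without the trend and 16 with the compared groups only; and over both media (1232 as reported), 335 without a filter, 551 without chromosomes 6, 8 and 11, and 2532 with both knockout libraries numbered 1 left out. LIF removal in knockout cells (816) gave 0 without a filter, and in wild type cells (985 by size) 1550 with a pseudocount of 0.1 and 536 at a mean of at least 5 FPKM. With a library left out, the counts ran from 4 to 14 with LIF, 5 to 16 after LIF removal, 5 to 994 over both media, 124 to 821 for LIF removal in knockout cells, 817 to 1924 over both genotypes and 0 to 1 for the difference of responses. A lone library is then assumed to vary like the others. The lowest counts over both media and over both genotypes came from leaving out a wild type library. The genotype effect then comes from a single medium, and the LIF removal effect from knockout cells alone.

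The labels give the knockout libraries a shared number across media and do not say what it marks. Deviations of number 1 from its group mean correlated at 0.366 across genes between media, a hint from the data and not the design. Hnrnpf was at 28.9% and 28.4% of wild type in the libraries numbered 1 and at 10.8% and 8.28% in those numbered 2, and chromosome 8 beyond 30 Mb had medians of 0.12 and -0.02 against -0.39 and -0.47. If the numbers mark clones, the 4 knockout libraries are 2 clones and the p-values of the knockout effect over both media are too small. With the number as a block the counts were 971 with LIF, 783 after LIF removal, 2621 for LIF removal in knockout cells, 2147 for knockout over both media, 3516 for LIF removal over both genotypes and 0 for the difference of responses. The block takes the spread between numbers out of the error.

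Of 3669 values of named genes under an alternative, 3346 kept direction and side of the threshold, 237 lost the call, 46 gained it and 40 changed sign. The sign changes concern 27 values, none of which had passed the threshold. With quantile normalization they were Pou5f1 with LIF (0.1367), Hnrnph2 after LIF removal (0.0197) and Hnrnph1 in the difference of responses (0.0028). With both libraries numbered 2 left out they were Dnmt3b (-0.0545) and Fgf5 (-0.2119), and with those numbered 1 left out Zfp42 (-0.2584), all over both media. With a library left out, the ranges with LIF were -0.3336 to 0.0380 for Eomes, -0.1547 to 0.2510 for Klf4 and -0.1101 to 0.1929 for Zfp42. After LIF removal they were -0.2855 to 0.3708 for Esrrb, -0.7411 to 0.0196 for Fgf5, -0.2540 to 0.0595 for Tfcp2l1 and -0.4067 to 0.6810 for Zfp42. For LIF removal in knockout cells they were -0.1915 to 0.3437 for Gata4, -1.0988 to 0.6429 for Hnrnpf and -0.0115 to 0.1545 for Hnrnph1. For the difference of responses they were -0.4018 to 0.3368 for Cdx2, -0.4278 to 0.1075 for Gata4, -1.0705 to 0.6712 for Hnrnpf, -0.1501 to 0.0160 for Hnrnph1 and -0.4481 to 0.6396 for Zfp42. For knockout over both media they were -0.5684 to 0.7096 for Dnmt3b, -0.6473 to 0.0427 for Esrrb, -0.3607 to 0.8170 for Fgf5, -0.0308 to 0.2509 for Hnrnph2, -0.1526 to 0.3847 for Nanog, -0.4175 to 0.9262 for Nes, -0.4383 to 0.3217 for Otx2 and -0.1506 to 0.3155 for Zfp42. For LIF removal over both genotypes they were -0.0082 to 0.2976 for Gata4 and -0.6401 to 0.3552 for Hnrnpf. None of the 24 list medians described changed sign under either scaling. Read depth is unknown, so what it limits could not be stated.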

Other observations

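The tests in this part were chosen after the results were seen.

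Several genes induced by interferon were higher in knockout libraries over both media. Of 27 tested members of a list drawn up after seeing the data, 15 passed over both media, all higher (18 adjusted over the list alone; median 1.001, and 0.888 after quantile normalization). In each medium alone none of the 27 passed over all genes tested (16 with LIF and 12 after LIF removal adjusted over the list alone, all higher), with medians of 1.035 and 0.746. Leaving out either wild type library gives the comparison in a single medium again, and with a knockout library left out 11 to 14 of the 27 passed over both media. Ifitm3, an antiviral membrane protein, rose by 1.29 over both media (limma adjusted p = 0.00184). With LIF it was at 127.9 FPKM in the wild type library and at 293 and 317 in the knockout libraries. The immunity-related GTPases Irgm1 (2.00), Igtp (1.53) and Irgm2 (1.43), the guanylate-binding proteins Gbp2 (1.79) and Gbp3 (1.83), Ifi35 (2.02), Isg15 (1.43), the transcription factor Irf1 (1.03) and the immunoproteasome genes Psmb8 (1.58) and Psmb10 (1.08) rose as well. Stat2 (-0.30, adjusted p = 0.355) and B2m (0.15, 0.476) did not pass. Of the 15, 6 lie on chromosome 11 and 8 on chromosomes other than 6, 8 and 11. Because members were chosen partly for having been seen to move, their number is not independent evidence.

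On the main axis of variation the knockout libraries with LIF (-25.7 and -12.6) lay between the wild type library with LIF (-39.9) and the libraries after LIF removal, wild type at 15.0 and knockout at 27.1 and 36.1. The knockout libraries were thus offset from wild type in the same direction in both media, by 14.2 and 27.3 with LIF and 12.1 and 21.1 after LIF removal, so the position with LIF is not particular to that medium. A hypothesis is that knockout cells with LIF may be shifted part of the way toward the state after LIF removal. It was tested on 9404 genes off chromosomes 6, 8 and 11, with no library shared: the difference of knockout library 1 from wild type with LIF was correlated across genes with the LIF removal response of number 2, and the reverse. Spearman's rho was 0.0882 and 0.246. The lower value lies between 0 and 0.1, the bounds set for the test, so the hypothesis was neither borne out nor excluded. With a similar offset after LIF removal, the position on the axis is not evidence for a partial response.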
